A study of Lumnitzera littorea with 6 samples.

How the data were processed

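Gene expression was measured by RNA sequencing in seedlings of the mangrove tree Lumnitzera littorea. Per the labels' protocols, seedlings 1 year old were kept under 12 h of light and 12 h of dark, and RNA was taken from leaves, shoots and roots together. The control group was kept at 25°C by day and 23°C by night for 48 h. The chilling group was kept at 8°C by day and 5°C by night, and the labels state no duration for it. Each group had 3 libraries, numbered 1 to 3 in their titles. Group and number were taken from the titles and each column of the table was matched to the title it spells. No column was left unmatched.

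The authors deposited 1 table of raw read counts per gene for the 6 libraries, with 26139 gene models and no normalization. The submitters' processing notes name FastQC (read quality), HISAT2 (alignment) and featureCounts (counting). Their versions, the genome build, the gene annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. Overlapping genes and near-identical copies can therefore share or lose reads in ways that cannot be followed from the counts. The values are whole numbers and their totals differ between libraries, from 27982493 to 41203847, as raw counts do. All rows carry a gene model identifier. The deposited table does not pair identifiers with gene names, and no genome, annotation or name table was used here. The 17 lists of functional genes fixed beforehand could not be applied, and checks of GC content, gene length and reads from other organisms were void because no gene had a value for them.

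Counts were analysed in R 4.3.3. Genes with low counts were removed with edgeR's filterByExpr at its defaults (a minimum count of 10 in a library of median size and 15 in total), which left 19487 genes holding 99.96% of all counts. Library sizes were scaled with the trimmed mean of M-values (TMM), whose factors were 1.15, 1.16 and 1.04 in control replicates 1 to 3 and 0.848, 0.865 and 0.979 in chilling replicates 1 to 3. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, robust settings, group as the only term), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05 on the adjusted p. A second count also asked for a fold change of at least 2. The standard error (SE) of a log2 fold change was derived from the F statistic. Normalised read counts are given as CPM, computed with the TMM-scaled library sizes, and log2 CPM values use a prior count of 2. Single values per library were compared with an exact two-sided permutation test, which cannot go below p = 0.1 with 3 libraries against 3. Counting intervals are exact 95% intervals on pooled counts and cover counting error only.

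On simulated counts for 19487 genes with the dispersions of this comparison, 200 of them changed, the test recovered 29 of 100 genes changed 4-fold and 1 of 100 genes changed 2-fold, with 2 false calls among 32. With 4000 changed genes, it recovered 76.5% of those changed 4-fold and 24.6% of those changed 2-fold, and 3.67% of its calls were false. A gene that missed the threshold was therefore not shown to be unchanged. The simulated genes varied independently of one another, without shifts shared by many genes of a library. The false share of 3.67% is thus not an error rate for the real libraries.

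Genes named individually followed a rule set before the data were examined. Among genes past the threshold, with an average log2 CPM at or above the median (4.24) and with groups whose CPM values did not overlap, the 2 with the largest and the 2 with the smallest log2 fold change were taken. This left 2074 higher and 1480 lower genes to rank. Alternatives set at the same time were median-of-ratios, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter, a filter of 1 CPM in at least 3 libraries, the replicate number as a block, leaving out each library, and leaving out the 100 most abundant genes. Fits without both libraries numbered 3, and with all libraries thinned to the smallest total, were added after seeing the data.

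No library repeated another. The chi-square statistic per degree of freedom between libraries of the same group was at least 102, so none agreed within sampling noise. The labels do not say that a shared number marks a shared plant, batch or day. Deviations from the group means correlated across genes at 0.051, -0.005 and -0.020 for same-numbered libraries 1, 2 and 3, so the numbers were not taken to pair the libraries. The labels give no sequencing batch or date.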

Results

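Transcript levels were profiled in seedlings of Lumnitzera littorea, an endangered mangrove tree, to ask which genes change under chilling. The 6 libraries fall into a control group (25°C day, 23°C night, n = 3) and a chilling group (8°C day, 5°C night, n = 3). Each library holds RNA from leaves, shoots and roots, in proportions that the labels do not state. A value is therefore a mixture with unknown weights. A difference in these proportions between the groups could not be told apart from a change within an organ. The stated 48 h applies to the control group only, so a difference in duration could not be excluded either. The total count was 41203847, 36161485 and 37454247 in control replicates 1, 2 and 3, and 27982493, 30658743 and 31610174 in chilling replicates 1, 2 and 3. All 3 control libraries were thus deeper than all 3 chilling libraries. The labels do not state that the libraries of a group came from separate plants, so p-values measure the spread between these libraries, which may be partly technical.

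The libraries separated by group. The first principal component of log2 CPM held 65.5% of the variance and separated the groups, with control libraries between -117.7 and -85.6 and chilling libraries between 71.7 and 123.9. Spearman correlations of counts across the tested genes were 0.925 to 0.967 for the 6 pairs within a group and 0.782 to 0.862 for the 9 pairs between groups; genes are not independent replicates. Chilling replicate 3 lay nearest to the control group on this axis, and control replicate 3 lay nearest to the chilling group. Genes varied somewhat more between chilling libraries, with a median SD of 0.37 in log2 CPM against 0.29 between control libraries, and 60.3% of tested genes had the larger SD under chilling. The chilling libraries were also shallower and include replicate 3, at 71.7 on the first component against 123.9 and 113.1 in replicates 1 and 2. The larger spread is therefore not shown to be an effect of chilling.

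**Figure D1:**
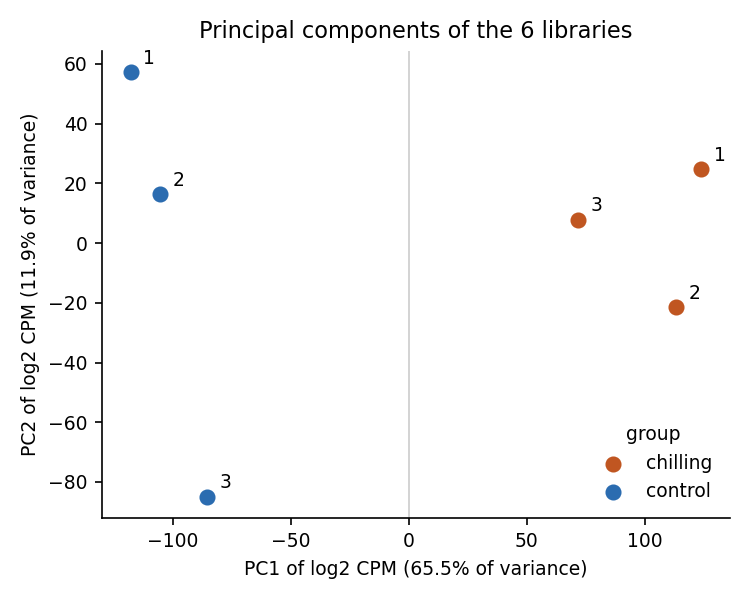
Each point is 1 library, numbered by replicate, on the first (x) and second (y) principal component of log2 CPM over the tested genes, which hold 65.5% and 11.9% of the variance. Control libraries (blue) lie between -117.7 and -85.6 on the first component, and chilling libraries (orange) between 71.7 and 123.9.

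The chilled seedlings differed from the controls in many of their measured genes. Of 19487 genes tested, 5999 (30.8%) changed, with 3160 higher and 2839 lower under chilling (edgeR quasi-likelihood test, adjusted p under 0.05, n = 3 per group). Genes that rose did so by a median log2 fold change of 1.93, and genes that fell did so by a median of -1.30. The 19 risen and 7 fallen genes without any count in one group were also set to the bound that 3 counts over the group allow. This could not move the medians, because the bounds were at least 23.2-fold and 8.43-fold, beyond the medians. Without control replicate 2, which left fewer calls, the medians were 2.65 and -1.62. In 5970 of the 5999 genes every chilling library lay on the same side of every control library. These genes were called on the same libraries, so this is no separate support. Over all tested genes, 50.7% had groups that did not overlap, where chance alone gives 10% for a single gene. Genes vary together, so the share over all genes can stray from 10% by chance. The other 13488 genes did not pass the test, among them 2437 with a fitted change of at least 2-fold.

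Changes of at least 8-fold were mostly increases. At least 2-fold changes were found in 4592 genes, of which 2622 rose and 1970 fell, so that 83.0% of the risen and 69.4% of the fallen genes reached this size. This 2-fold order turned with upper-quartile factors (2291 rose, 2719 fell) and with total counts (2047 rose, 3440 fell). At least 8-fold changes were found in 887 risen and 189 fallen genes. Risen genes outnumbered fallen genes at 8-fold under each of the other scalings, with 743 against 306 by total count alone. The balance over all calls, like that at 2-fold, depended on the scaling. Risen genes made up 52.7% of calls with TMM, 41.2% with upper-quartile factors and 33.7% with total counts, as the median log2 fold change of all tested genes moved from -0.02 to -0.19 and -0.33. The number of calls also moved when 1 library was left out. It was 3484, 2581 and 4733 without control replicates 1, 2 and 3. Without chilling replicates 1, 2 and 3 it was 2712, 4141 and 6352. A fit with 1 library fewer can lose calls for that reason alone, and this was not separated from dependence on a particular library. Fallen genes numbered 1786 without chilling replicate 2. The 8-fold counts fell to 568 risen and 97 fallen without chilling replicate 1. Without control replicate 2, 103 genes fell at least 8-fold.

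**Figure D2:**
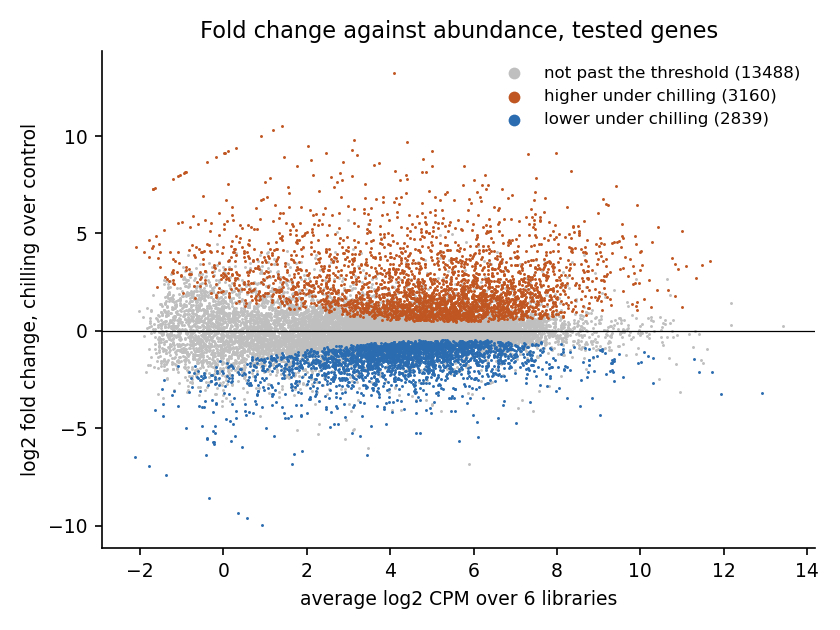
Each point is 1 of 19487 tested genes, with its average log2 CPM over the 6 libraries (x) and its log2 fold change of chilling over control (y). The 3160 genes higher under chilling (orange) reach farther from 0 than the 2839 lower genes (blue), and genes that did not pass the threshold are grey.

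Calls were more frequent among transcripts abundant on average over the 6 libraries, where risen genes prevailed. Tested genes were divided into 5 classes of equal size by average log2 CPM over all 6 libraries. A gene's level under chilling thus helped to place it. Among the 1000 genes with the highest mean CPM in the control group, 207 fell and 98 rose under chilling. Among the chilling group's top 1000, 519 rose and 37 fell. Each of these lists was picked by 1 group's level, which favours its direction. The prevalence of risen genes was therefore not shown for the control level. In the most abundant class, 38.7% of genes changed, and 1076 rose while 434 fell. In the least abundant class, 18.0% of genes changed, and 404 rose while 298 fell; this lowest class had more fallen than risen genes with upper-quartile factors (404 fell, 356 rose) and with total counts (479 fell, 314 rose). In the most abundant class risen genes stayed ahead with total counts, at 877 against 758. In classes 2 and 3, counted from the lowest, fallen genes were the more numerous, with 655 against 429 and 786 against 539. These numbers moved when 1 library was left out, and a fit with 1 library fewer can lose calls for that reason alone. The changed share of the most abundant class was 24.8% without control replicate 1, 19.4% without control replicate 2 and 19.7% without chilling replicate 1, with 725, 571 and 621 risen and 242, 187 and 145 fallen genes. That of the least abundant class was 7.49%, 4.67% and 5.28% without these libraries, 11.5% without control replicate 3 and 9.83% without chilling replicate 2; without control replicate 2 it held 120 risen and 62 fallen genes. Without control replicate 2, fallen genes numbered 225 against 182 in class 2 and 340 against 238 in class 3. The order of risen and fallen genes in these 4 classes held in each of the 6 fits that left out 1 library. The least abundant class has the fewest counts, which can limit what the test calls there. With all libraries thinned to the smallest total, it held 381 risen and 296 fallen genes.

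**Figure D3:**
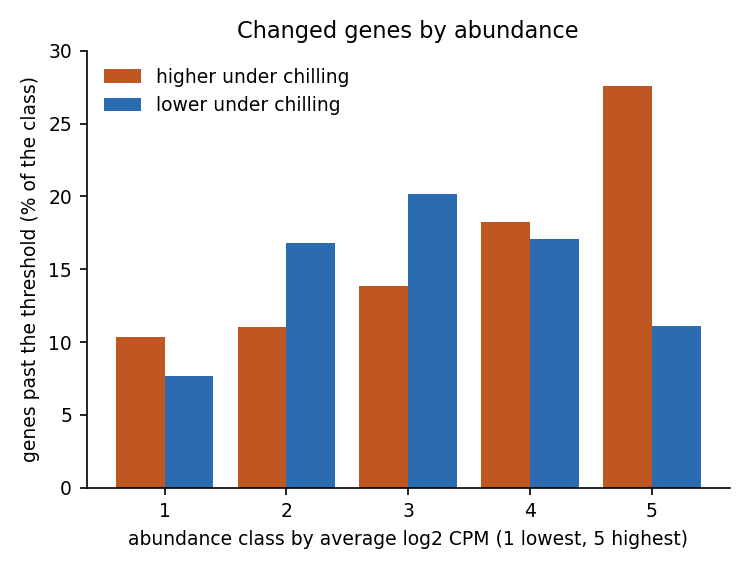
Bars give the percentage of tested genes that passed the threshold in each of 5 equal classes of average log2 CPM (x), from the lowest (1) to the highest (5), for genes higher (orange) and lower (blue) under chilling with TMM scaling. In the most abundant class 27.6% of genes were higher and 11.1% lower; in the lowest class, where 10.4% were higher and 7.6% lower, the order turns with upper-quartile and total-count scaling.

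Much of the top of the transcript ranking differed between the groups. Of the 100 genes with the highest mean CPM in the control group, 40 were also among the top 100 of the chilling group. The other 9 ways to split the 6 libraries into 3 and 3 gave 65 to 83 shared genes. Each side of those splits holds libraries of both groups, which raises the sharing when the groups differ. How much of the turnover comes from spread between libraries of the same group was not measured. Among the control group's top 100, 28 fell and 2 rose under chilling. Among the chilling group's top 100, 54 rose and 3 fell. Both lists were picked by the level in one group, which favours these directions. For the top 1000, 513 genes were shared, against 690 to 842 in the other splits.

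The genes that rose took 10.7% ± 0.55 of all counts in control libraries and 38.9% ± 4.86 in chilling libraries (SD, n = 3; exact permutation test, two-sided p = 0.1, the smallest possible). The genes that fell took 22.4% ± 2.20 and 6.33% ± 1.17 (SD, n = 3; exact permutation test, p = 0.1). These genes were called on the same libraries, so the shares describe the size of the change and are not independent evidence for it. The 10 most abundant genes of each library held 7.01% ± 1.15 of counts in control and 4.91% ± 0.36 in chilling libraries, with no overlap between the groups (SD, n = 3; exact permutation test, p = 0.1). The control group's most abundant gene alone took 1.56% ± 0.75 in control and 0.134% ± 0.078 in chilling libraries (SD, n = 3). Its second gene took 1.09% ± 0.57 and 1.07% ± 0.18 (SD, n = 3). For the 100 most abundant genes the shares overlapped, at 20.4% ± 0.97 and 18.5% ± 0.70 (SD, n = 3; exact permutation test, p = 0.2). For the top 1000 the order was the opposite, at 46.6% ± 1.74 and 50.0% ± 1.55 (SD, n = 3; exact permutation test, p = 0.1). The number of genes with at least 1 count was 21170 ± 107 in control and 21098 ± 105 in chilling libraries (SD, n = 3; exact permutation test, p = 0.4). Genes with at least 10 counts numbered 19306 ± 99.4 in control and 19157 ± 54.7 in chilling libraries, without overlap (SD, n = 3; exact permutation test, p = 0.1), in libraries that were also deeper in the control group. With all libraries thinned to the smallest total, the number with at least 1 count was 21090 ± 133 and 21081 ± 113 (exact permutation test, p = 0.9, n = 3).

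A small set of genes was detected under one temperature alone. Without a count in any control library, 19 genes had at least 10 counts in every chilling library, and the median of this set was at least 60.7-fold higher under chilling when control is set to 3 counts over the group. In the reverse direction there were 7 such genes, with a median at least 38.8-fold lower under chilling. No other split of the libraries gave more than 2 genes of this kind, but those splits mix the groups and so make such genes unlikely. A count of 0 in these libraries bounds the level and does not show that a gene was silent. The limit of 10 counts was chosen after seeing the data.

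The genes named by the fixed rule were 2 that rose and 2 that fell. The gene model gene.evm.model.3.149 rose from 0.0489 ± 0.0478 CPM in control to 42.2 ± 12.4 CPM under chilling (SD, n = 3), a log2 fold change of 9.70 with SE 0.70 (edgeR adjusted p = 0.00185). Its control value rests on 6 counts against 3371 under chilling, and the pooled ratio was 889 with a 95% counting interval of 408 to 2424. Its log2 fold change was 9.08 without control replicate 1 and 10.60 without control replicate 2. The gene model gene.evm.model.7.731 rose from 0.105 ± 0.122 to 64.2 ± 53.9 CPM (SD, n = 3), a log2 fold change of 9.24 with SE 1.32 (edgeR adjusted p = 0.00593). Its chilling libraries ranged from 12.5 CPM in replicate 3 to 120.1 CPM in replicate 2, and limma-voom gave an adjusted p of 0.0735. Its log2 fold change was 8.61 without control replicate 1, 10.68 without control replicate 2 and 8.42 without chilling replicate 2. The gene model gene.evm.model.31.81 fell from 134.2 ± 33.6 to 3.04 ± 3.15 CPM (SD, n = 3), a log2 fold change of -5.46 with SE 0.81 (edgeR adjusted p = 0.00657). Chilling replicate 2 holds 177 of its 243 chilling counts, and without that library the log2 fold change was -6.77 (edgeR adjusted p = 0.00431). The gene model gene.evm.model.6.626 fell from 97.6 ± 133.6 to 1.94 ± 2.28 CPM (SD, n = 3), a log2 fold change of -5.66 with SE 1.58 (edgeR adjusted p = 0.0371). Its control mean rests on replicate 2, at 251.9 CPM against 21.3 and 19.7 in the others, and without that library the log2 fold change was -3.42 (edgeR adjusted p = 0.0923). It was -7.17 without chilling replicate 1 (edgeR adjusted p = 0.0669), and the call was also lost without chilling replicate 2 or 3 (adjusted p = 0.0767 and 0.101). With limma-voom, and in edgeR with the replicate number as a block, the adjusted p was 0.12. The call was lost in 7 of the 16 alternatives that gave an adjusted p for this gene model, and DESeq2 gave none. The function and the genomic position of these gene models are not analysed here, since the table gives identifiers only.

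**Figure D4:**
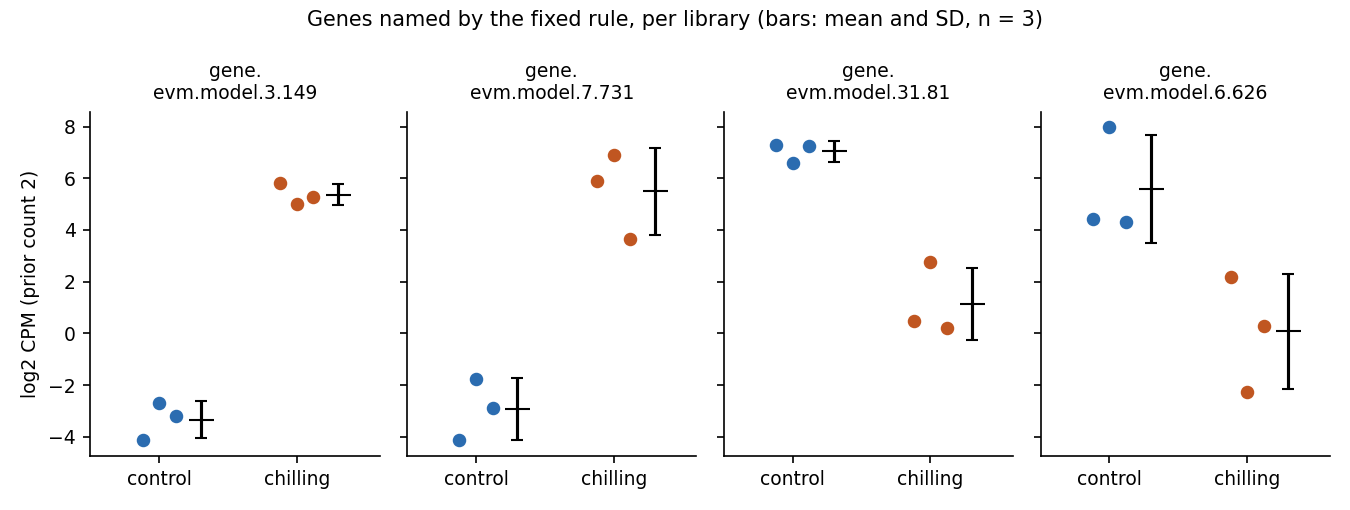
Points are the log2 CPM (y, prior count 2) of the named gene models in each of the 3 control (blue) and 3 chilling (orange) libraries; the black marks give the mean and SD of each group. In gene.evm.model.3.149 the chilling libraries lie between 5.02 and 5.81 and the control libraries between -4.13 and -2.71. These control values rest on 0, 4 and 2 counts in replicates 1, 2 and 3, so the prior count weighs heavily in them. In gene.evm.model.6.626 control replicate 2 stands at 7.98, above the other control libraries at 4.42 and 4.30.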

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

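Of the alternatives, the fits without both libraries numbered 3 (5973 genes changed, 4572 of them among the 5999) and with all libraries thinned to the smallest total (5970) were chosen after seeing the data. No gene called in the main fit and under an alternative changed direction in any of the 17 alternatives. Median-of-ratios factors, limma-voom, either filter and leaving out the 100 most abundant genes kept all 6 counts within 1.5 times, and so did DESeq2, with 8290 genes changed. Upper-quartile factors also stayed within 1.5 times but turned the order at 2-fold or more, with 2291 higher and 2719 lower genes in place of 2622 and 1970. Total counts gave 4530 lower genes in place of 2839, and at 2-fold or more 2047 higher and 3440 lower; the factors differ between the groups, which shifts every gene alike. Leaving out 1 library gave 2581 to 6352 changed genes, 1460 to 3319 higher and 1121 to 3033 lower, and at 2-fold or more 2446 to 4853 changed, 1428 to 2727 higher and 978 to 2126 lower. The lowest counts came without control replicate 2 or chilling replicate 1, and the highest without chilling replicate 3. The genes lost without control replicate 2 had a median adjusted p of 0.0794 (edgeR), just past the threshold, in a fit with 1 library fewer. With the replicate number as a block, 3522 genes changed, 1954 higher and 1568 lower; 3359 of them were in the main fit. The block leaves 2 residual degrees of freedom in place of 4, the libraries share only a number, and not every library correlated best with its own number. The call of gene.evm.model.6.626 was lost in 7 of 16 alternatives (adjusted p 0.0249 to 0.12; DESeq2 gave it none), that of gene.evm.model.7.731 in 1 of 17 (limma-voom), and those of gene.evm.model.3.149 and gene.evm.model.31.81 in none of 17. The share of counts in the most abundant genes, chilling minus control, was -1.89 percentage points for the top 100 (p = 0.2), -2.10 for the top 10 and 3.42 for the top 1000 (exact permutation tests, p = 0.1 for both, n = 3). The comparison of gene lists was not run, because identifiers are not paired with names. Low counts can limit the calls in the least abundant class, where average log2 CPM ends at 1.96, but by how much was not tested.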

Other observations

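The tests of explanations in this part were written down before their results were seen. The patterns they bear on had already been noticed in the data. The test of consecutive pairs with a positive correlation within groups was an exception. No prediction was written for the share of pairs going the same way, for larger distances or for runs. Gene models with consecutive numbers in their identifiers tended to change together under chilling. Among 11136 pairs of tested genes with the same first number and consecutive second numbers, log2 fold changes correlated with a Spearman rho of 0.141, where 1000 shufflings of genes within their first number gave at most 0.040. Where both genes of such a pair changed, 756 of 1146 pairs (66.0%) went the same way, against 50.1% for unrelated genes. The correlation was 0.062 at a distance of 2 numbers, 0.037 at 3 and 0.010 at 5. Runs of 3 or more consecutive numbers that all rose numbered 51, the longest with 6 genes, and runs that all fell numbered 39, the longest with 4. The shufflings gave at most 46 and 35 such runs, with means of 28.6 and 19.3. These correlations are across genes, which are not independent replicates.

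A candidate explanation is that neighbouring gene models respond in common, if the numbers follow their order on the assembly, which was not checked; the rho of 0.141 is the pattern itself and does not decide this. Similar abundance of the paired genes is argued against, since pairs of unrelated genes matched on average log2 CPM reached a rho of at most 0.035. Reads shared by adjacent copies, or 1 gene split into 2 models, remain open. In the 4829 consecutive pairs whose deviations within groups did not go together (r of 0 or below), the rho was 0.008, inside the range of the shufflings, whose highest value was 0.066. In the other 6307 pairs, with r above 0, it was 0.24, above the highest shuffling of 0.064. Shared reads and common control of neighbours both predict this difference, and r from 6 libraries sorts single pairs only roughly. Deviations within groups may also carry part of the chilling change, as chilling replicate 3 lay nearer to the controls (below). Sorting pairs by r then partly sorts them by the agreement of their changes, so this split cannot decide between the explanations.

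Chilling replicate 3 lay nearer to the control libraries than the other chilling libraries did. Each library was placed between the groups on genes called at 2-fold or more without it, with 0 at the mean of the other group and 1 at the mean of its own. Chilling replicate 3 had a median position of 0.707 over 4775 of the 4853 genes so called. It was 0.707 for risen and 0.707 for fallen genes. Chilling replicates 1 and 2 lay at 1.09 and 0.983, over 2441 and 3554 genes, and the control libraries at 0.996, 0.963 and 0.850. The gene sets thus differ. The chilling mean used for replicates 1 and 2 includes replicate 3, which raises their positions, so their gap to 0.707 is partly built in. Depth is argued against, because the position of chilling replicate 3 was 0.706 with all libraries thinned to the smallest total. Control RNA mixed into the library as the whole cause is argued against too. Of the 1007 genes that rose at least 8-fold without chilling replicate 3, the 937 examined would need a share of 59.6% (quartiles 30.6% to 79.6%). Of the 218 genes that fell at least 8-fold, 214 were examined. Over these, its level was a median of 14.2% of the control mean (quartiles 6.64% to 23.7%), against 8.35% in the other chilling libraries. A smaller or earlier response of the plants behind this library, and another proportion of leaves, shoots and roots, stay open as untested, since tissue markers could not be identified without gene names.

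The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split was the only one, 1 of 10, with counts as large for all changed genes (5999), higher genes (3160), lower genes (2839) and their counts at 2-fold or more (4592, 2622 and 1970). The highest count among the other splits was 0 for each of the 6. Each of those splits mixes libraries of both groups, so a difference between the groups adds to the spread within each side. Few or no calls were therefore likely beforehand, and the 0 is no separate support for the counts.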
